A study of Mus musculus with 20 samples.

How the data were processed

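RNA-seq was made from 12 libraries and small RNA-seq from 8, in 4 groups each (3 sorted states and the total population), after cell sorting, Trizol extraction and DNase treatment per the labels' protocols. The RNA-seq libraries were rRNA-depleted and strand-marked with dUTP, and the small RNA libraries were made by adapter ligation. The submitters' processing notes name STAR 2.4.1d, RSEM 1.2.30 and the builds mm10 and GRCm38, with no order or role; the names of the deposited tables point to GENCODE M15, miRBase and EBSeq. How libraries were scaled and merged into 1 value per group is not given in the sources used here.

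In both deposited tables the authors give a normalized signal per feature and group, neither counts nor scaled to a fixed total, per the file headers and the values. In the same tables the authors give a score per feature for each of 15 patterns of equal and unequal groups, the EBSeq posterior probability, and a score for any difference. The ratios between states in the deposited RNA-seq table were not used, since they hold spreadsheet errors where a state is 0, and were recomputed from the group values. The 15 patterns are not spelled out in the tables. They were read in the EBSeq order for 4 conditions in the column order state 3, state 2, state 1, total population. This was checked on features with a pattern score of at least 0.95 and a mean of at least 5: groups set equal by the pattern lay closer together than groups set apart in 94.4% of 1453 RNA-seq features and 93.8% of 161 small RNA features, and the next best order, which exchanges state 1 and the total population, gave 90.8% and 78.3%. Under that order the calls of state 1 and of the total population would change places.

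From these, the probability that 2 groups differ was computed as the sum of the scores of all patterns that set them apart, and a difference was called at 0.95 or more, with its direction from the group values. Because the tables hold a single value per group, the count tests, limma, the camera gene list tests and the adjustment over a list alone that were planned for values per library were not run, and no p-value was computed. Called counts, named genes and lists therefore rest on the authors' model and on the pattern order inferred above. The labels do not say that the libraries came from separate cultures, so the posteriors may measure technical spread only. Log2 ratios are log2((value + 1)/(value + 1)). Each gene list was fixed before the data were examined, as were the rule for named genes, the comparisons and most alternatives. A list is given by the number of members that rose, fell or were not called and by its median log2 ratio, set against 10000 random lists of the same size matched on mean expression (20 bins for genes, 10 for hairpins). Of the 25 gene lists, 18, 16 and 21 had a median outside the central 95% of the random lists for state 2 against state 1, state 3 against state 2 and state 3 against state 1, and of the 11 microRNA lists 4, 4 and 5. These percentiles describe the tables and are not tests.

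Named genes were Nanog, Sox2 and Pou5f1, the 5 largest rises and 5 largest falls per comparison among called genes with at least 5 on a CPM-like scale (the value over its column total), without predicted gene models, pseudogenes and small RNA classes, and from each list up to 4 called members with the largest change or, with none called, the 2 most abundant. For microRNAs the minimum was 10 on this scale and the 4 most abundant members of each list were taken; the requirement of a like direction in every replicate pair could not be applied. Other genes are named where they make up a small count. MicroRNA values are for hairpins; mature arms are not separated, and hairpins that share a mature sequence divide its reads in a way the sources used here do not state. Features without a name (18 RNA-seq and 165 small RNA features, 0.0195% and 0.0220% of the state 1 total) stayed out of lists and names. Coordinates are from the RefSeq genes of GRCm38, matched by symbol for 457 of 474 genes and 177 of 185 hairpins.

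Depth was read from the commonest low value of a column, taken as the worth of 1 read over the group: about 55.4, 60.4, 48.0 and 52.1 M RNA-seq reads or read pairs stand behind state 1, state 2, state 3 and the total population, and about 10.9, 9.26, 8.42 and 5.61 M small RNA reads. A value of 0 allows up to about 3 reads over the group, or 0.84 to 1.08 in the RNA-seq table and 0.93 to 2.22 in the small RNA table, for counting error only. These are estimates, since libraries of a group are merged. In the RNA-seq table the noncoding gene Gm26917 took 10.4% to 12.6% of a column.

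The pattern sums and list percentiles were tested on simulated tables with 200 changed features: 100.0% of the 139 genes set apart between state 2 and state 1 were recovered among 29692 with 0 false calls. Over all comparisons and both tables, 96.2% to 100.0% of directions were right. The simulated scores were written in the same pattern order in which they were read, so the recovery was set in advance. It checks the code of the sums, and neither that order nor the authors' model. Alternatives were a pseudocount of 0.1, a mean value of at least 5, median-ratio and quantile rescaling, protein-coding genes or hairpins alone, scaling to the microRNA total, and an absolute log2 ratio of at least 1; a threshold of 0.99, calls from the most probable pattern and scaling to the median hairpin were chosen after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.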

Results

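Mouse embryonic stem cells, the cultured pluripotent cells of the early embryo, were grown in serum with leukemia inhibitory factor (LIF). They were sorted by flow cytometry into 3 states by their levels of the pluripotency factors Nanog and Sox2. State 1 was high for both factors, state 2 was low for Nanog and high for Sox2, and state 3 was low for both. The unsorted total population was the 4th group. RNA-seq after rRNA depletion covered 12 libraries, 3 per group, and small RNA-seq covered 8 libraries, 2 per group. The tables used here hold 1 value per feature and group, set by the authors. The values therefore carry no spread between libraries and no test could be run on libraries. The RNA-seq table lists 29692 genes, with column totals of 17.7, 16.9, 17.3 and 17.2 M (value units) for state 1, state 2, state 3 and the total population. The small RNA table lists 26278 features, among them 605 microRNA hairpins (the precursors from which mature microRNAs are cut), with column totals of 5.13, 3.43, 2.61 and 4.15 M. A difference was called where the pattern probabilities of the authors' deposited table summed to at least 0.95 for unequal groups. These sums were made here, with the pattern order inferred as described above, and are not calls made by the authors. Log2 ratios were computed on the value plus 1, which understates the change of low genes.

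The sort was checked first on the genes that define it. Nanog (ENSMUSG00000012396.12; chromosome 6, 122707489 to 122714633 in GRCm38), the homeodomain factor of ground-state pluripotency, fell from 4145 to 743 (log2 -2.48) between state 1 and state 2 and to 440.0 in state 3 (log2 -0.76 against state 2). Sox2 (ENSMUSG00000074637.7; chromosome 3, 34649995 to 34652461), the partner of Oct4 on pluripotency enhancers, fell less between state 1 and state 2, from 4155 to 3167 (log2 -0.39), and then to 1306 in state 3 (log2 -1.28). Pou5f1 (ENSMUSG00000024406.16, chromosome 17, 35506032 to 35510777), which encodes Oct4, had values of 13810.4 in state 1, 10275 in state 2 and 9826 in state 3. It was not called, with posteriors summed from the authors' deposited patterns of 0.927 for state 2 against state 1 and 0.931 for state 3 against state 1. The order of Nanog and Sox2 followed the labels of the 3 states.

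**Figure D1:**
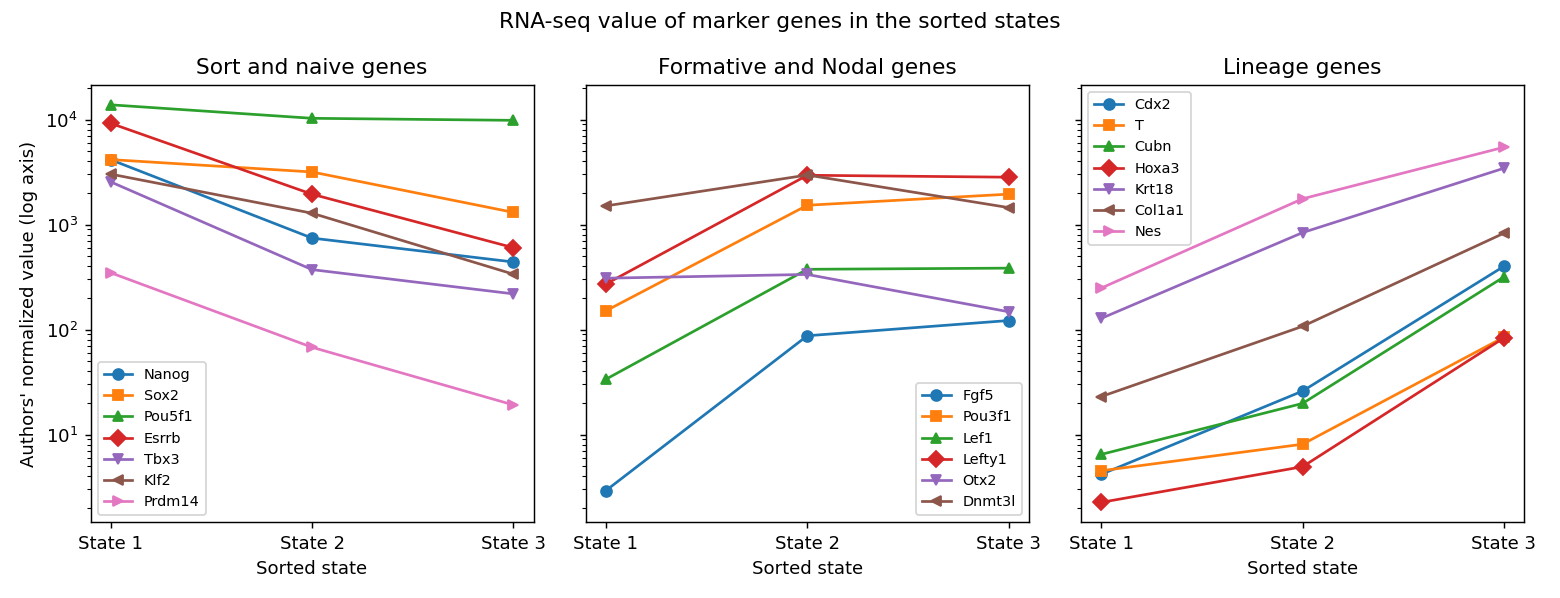
Values of genes in the 3 sorted states on a log axis; each point is the authors' normalized value of the state and lines join the points of a gene. Nanog was 4145 in state 1 and 440.0 in state 3, Fgf5 was 2.93 and 122, and Cdx2 was 4.18 and 400.1.

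The comparison of state 2 with state 1 asks what differs between cells that were both sorted as high for Sox2 and part in Nanog. Sox2 RNA was also called lower in state 2 (log2 -0.39), so the step does not isolate Nanog. Naive pluripotency genes fell: 20 of the 25 measured members of the list were lower in state 2 and 0 were higher, with a median log2 ratio of -1.57. Nanog, a gene used for the sort, is counted among these falls and in the median. Tbx3, a T-box factor of the naive network, fell from 2549.5 to 372 (log2 -2.77). Jam2, a junction adhesion molecule, fell from 1572 to 249 (log2 -2.65), and Prdm14, a repressor of FGF signalling and DNA methylation genes, fell from 347 to 67.8 (log2 -2.34). Genes of the formative and primed epiblast, the later pluripotent tissue of the embryo, moved the other way, with 12 of 20 members higher, 1 lower and a median of 1.05. Fgf5, a growth factor of the post-implantation epiblast, rose from 2.93 to 87.3 (log2 4.49), Pou3f1, a POU factor of the primed state, from 151 to 1526 (log2 3.33), and Lef1, a nuclear effector of Wnt signalling, from 33.6 to 375 (log2 3.44).

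Sums of the authors' deposited probabilities called 3990 genes between state 2 and state 1, 2111 higher and 1879 lower in state 2. The expected false share by the same sums was 0.453%. The 5 largest rises among abundant genes were Cnr1, a cannabinoid receptor (from 4.21 to 166), Sema6a, a transmembrane semaphorin (from 45.0 to 1199, log2 4.71), Trim67 (log2 4.70), Vrtn (log2 4.67) and Zfp608 (log2 4.54). The 5 largest falls were Inhbb, an inhibin and activin subunit (from 2201 to 298, log2 -2.88), Tbx3, Jam2, Msc, a helix-loop-helix repressor (log2 -2.63), and Aqp3, a water and glycerol channel (log2 -2.50).

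Signalling readouts split by pathway. LIF and STAT3 targets fell in 8 of 12 cases and rose in 2: Lifr, the LIF receptor, fell from 3032 to 1438 (log2 -1.08). Junb, an AP-1 subunit, rose from 592 to 1038 (log2 0.81). Nodal and BMP targets rose in 6 of 11 cases with 0 falls. Lefty1, a feedback inhibitor of Nodal, rose from 272 to 2947 (log2 3.43). FGF-ERK targets rose in 6 and fell in 4 of 14 cases, with Dusp5, a MAP kinase phosphatase, up by 1.21 and Etv4, an ETS factor, at -0.98 on the log2 scale. Of 12 Wnt targets, 1 rose and 2 fell (median 0.11), among them Notum, a Wnt deacylase, from 199.9 to 46.1 (log2 -2.09). Immediate-early and dissociation stress genes rose in 12 of 16 cases, Jun from 186 to 623 (log2 1.74) and Egr1 from 149 to 466 (log2 1.64). The p53 targets rose in 9 of 16, with 1 lower; Cdkn1a, the p21 cell cycle inhibitor, rose from 247 to 455 (log2 0.88).

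Of 20 trophectoderm genes 9 rose and 3 fell, with Krt19 and Krt7, keratins of simple epithelia, up by 3.23 and 3.52 on the log2 scale. Of 23 primitive endoderm genes 5 rose and 2 fell; the risers included Foxa2, a forkhead factor of endoderm (from 5.77 to 143, log2 4.42), and Col4a1, a basement membrane collagen (from 277 to 1767, log2 2.67). Of 25 mesendoderm genes 4 rose, Wnt3, a primitive streak ligand, from 4.84 to 51.0 (log2 3.15), and 1 fell, which was Bmp4, from 569 to 103 (log2 -2.45). Of 21 neuroectoderm genes 3 rose, Nes, the intermediate filament nestin, from 248 to 1759 (log2 2.82), and 2 fell. None of the 23 Hox genes was called, but their median log2 ratio of 0.78 lay above the central 95% of random lists. Hoxb9, opposite to that median, had values of 33.9 in state 1 and 19.3 in state 2. Genes of the feeder fibroblast list, chosen as markers of a cell type that ESC cultures can hold, rose in 9 of 19 cases with 0 falls, Thbs1, a matrix glycoprotein, from 46.6 to 819 (log2 4.11), and Tagln, an actin-binding protein of contractile cells, from 70.2 to 978 (log2 3.78). Cytoskeleton and epithelial-mesenchymal transition genes rose in 12 of 21 cases and fell in 1, with Cdh2, N-cadherin, up by 2.83 on the log2 scale.

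Among general pluripotency genes 3 rose, 4 fell and 13 of 20 were not called. Sox2, a gene used for the sort, is counted among these falls. Cdh1, E-cadherin, rose from 7766 to 12924 (log2 0.73), and Alpl, alkaline phosphatase, fell from 2272 to 1252 (log2 -0.86). G2/M genes fell in 11 of 20 cases with 0 rises, Aurka, a mitotic kinase, from 2178 to 1451 (log2 -0.59). G1 and S genes rose in 5 and fell in 7 of 20 cases, with Cdkn1c, the p57 inhibitor, up by 1.45 and Ccnd3, cyclin D3, at -1.38 on the log2 scale. DNA methylation and chromatin genes rose in 3 and fell in 7 of 20 cases; Dnmt3l, a cofactor of de novo methyltransferases, rose from 1505 to 2962 (log2 0.98), and Tet1, a 5-methylcytosine dioxygenase, fell from 22009.6 to 13765 (log2 -0.68). Of 19 germline genes 2 rose and 1 fell, of 19 glycolysis genes 3 rose and 3 fell, and of 19 microRNA pathway genes 2 rose and 1 fell. In the 2-cell-like list 1 of 20 genes fell, the translation factor gene Eif1a (log2 -0.25); the Zscan4 and Usp17l members share near-identical copies and their values are uncertain. None of the 13 mitochondrially encoded genes was called, but their median log2 ratio of 0.50 lay above the central 95% of random lists, beside the rises of the stress and lineage lists. The most abundant members, mt-Co1 and mt-Nd1, had log2 ratios of -0.0640 and 0.0775. Of 11 microRNA host genes 2 rose and 1 fell, among them Sfmbt2, which carries a microRNA cluster in an intron, from 568 to 2133 (log2 1.91).

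The comparison of state 3 with state 2 asks what accompanies lower Sox2 in cells that were both sorted as low for Nanog. Nanog RNA also fell in this step, from 743 to 440.0, so the step does not isolate Sox2. Genes of several differentiated lineages rose together in state 3. Hox genes, which Polycomb complexes keep silent in ESC, rose in 17 of 23 cases with 0 falls, Hoxa3 from 4.94 to 83.2 (log2 3.83) and Hoxa9 from 1.80 to 35.2 (log2 3.69). Primitive endoderm genes rose in 15 of 23 cases and fell in 1. Cubn, the endocytic receptor cubilin of visceral endoderm, rose from 19.8 to 317 (log2 3.94), Pdgfra, a receptor tyrosine kinase of primitive endoderm, from 4.55 to 43.1 (log2 2.99), and Sox17, an endoderm factor, from 2.65 to 23.6 (log2 2.75). Trophectoderm genes rose in 10 and fell in 2 of 20 cases, with Cdx2 (chromosome 5, 147300900 to 147307249), a caudal factor of trophectoderm and posterior mesoderm, from 25.9 to 400.1 (log2 3.90). Mesendoderm genes rose in 9 of 25 cases with 0 falls, T, the primitive streak factor brachyury, from 8.09 to 84.6 (log2 3.23). Neuroectoderm genes rose in 5 of 21 cases and fell in 1, which was Neurod1 (log2 -1.37).

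Sums of the authors' deposited probabilities called 2552 genes between state 3 and state 2, 1605 higher and 947 lower in state 3. The expected false share by the same sums was 0.655%. The largest rises among abundant genes were Cubn, Cdx2, Cd44, a hyaluronan receptor (from 19.2 to 166, log2 3.05), Prss23, a serine protease (from 42.5 to 344, log2 2.99), and Col1a1, the alpha-1 chain of type I collagen (from 107 to 827, log2 2.94). The largest falls were Dppa3, a maternal and naive factor also called Stella (from 167 to 26.5, log2 -2.61), Cpsf4l (log2 -2.11), Inpp5d, an inositol phosphatase (log2 -2.10), Klf2, a Krüppel-like factor of the naive network (from 1282 to 337, log2 -1.93), and Tdh, threonine dehydrogenase of mouse ESC (from 3349 to 902, log2 -1.89).

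Naive pluripotency genes fell again in 19 of 25 cases, the sort gene Nanog among them, with 0 rises (median log2 -1.23). General pluripotency genes fell in 5 of 20, the sort gene Sox2 among them, with 0 rises. Dppa5a, a pluripotency-associated RNA-binding protein, fell from 7939 to 3961. The formative and primed list had 4 rises and 4 falls among 20 genes; Krt18, a simple epithelial keratin, rose from 838 to 3437 (log2 2.03), and Otx2, a homeodomain factor of the formative state, fell from 335 to 148 (log2 -1.17). Dnmt3l fell from 2962 to 1449.8 (log2 -1.03), so that state 2 held its highest value of the 3 states; in its list 1 gene rose and 5 fell. Cytoskeleton and epithelial-mesenchymal transition genes rose in 18 of 21 cases with 0 falls, Vim, the mesenchymal filament vimentin, from 1065 to 4829 (log2 2.18). Genes of the feeder fibroblast list rose beside these lineage genes in 10 of 19 cases with 0 falls, Col3a1, a fibrillar collagen, from 21.4 to 167 (log2 2.91). The fibroblast markers Dcn and Thy1 had values of 2.09 in state 2 and 12.4 in state 3 and of 42.0 in state 2 and 59.3 in state 3 and were not called.

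G2/M genes fell in 12 of 20 cases with 0 rises, Top2a, a topoisomerase of dividing cells, from 10464 to 7079 (log2 -0.56). FGF-ERK targets rose in 6 of 14 cases, Wnt targets in 5 of 12 and Nodal and BMP targets in 3 of 11, with 0 falls in each list. Emp1, an epithelial membrane protein, rose from 55.5 to 419.6 (log2 2.90), and Dkk1, a secreted Wnt inhibitor, from 3.49 to 18.7 (log2 2.13). LIF and STAT3 targets were not called in 11 of 12 cases. Immediate-early and stress genes rose in 3 of 16, p53 targets rose in 1 and fell in 2 of 16 (median 0.015), and germline genes fell in 4 of 19. G1 and S genes rose in 2 of 20 cases (median -0.059), glycolysis genes rose in 3 and fell in 2 of 19, and 1 of 19 microRNA pathway genes rose. No member of the 2-cell-like, microRNA host and mitochondrially encoded lists was called from the authors' deposited probabilities for this comparison.

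The ends of the series, state 3 against state 1, set Nanog-low and Sox2-low cells beside cells high for both. Naive genes fell in 24 of 25 cases, the sort gene Nanog among them, with 0 rises and a median log2 ratio of -2.75. Esrrb, an orphan nuclear receptor of the naive network, fell from 9206 to 602 (log2 -3.93), and Prdm14 had a log2 ratio of -4.11. Called lineage genes were mostly higher. Hox genes rose in 17 of 23 cases (median 3.38), primitive endoderm genes in 14 of 23 with 2 falls (median 2.29), and trophectoderm genes in 14 of 20 with 3 falls (median 1.90). Mesendoderm genes rose in 12 of 25 cases with 1 fall and 12 not called (median 1.31), and neuroectoderm genes in 6 of 21 with 1 fall and 14 not called (median 0.57). Cdx2 rose from 4.18 to 400.1 (log2 6.27), T from 4.52 to 84.6 (log2 3.95) and Nes from 248 to 5446 (log2 4.45).

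Sums of the authors' deposited probabilities called 6070 genes between state 3 and state 1, 3394 higher and 2676 lower in state 3. The expected false share by the same sums was 0.356%. The largest rises among abundant genes were Gbp2, an interferon-induced GTPase (from 1.94 to 247, log2 6.40), Cdx2, Thbs1 (from 46.6 to 3678, log2 6.27), Csf1, the macrophage colony-stimulating factor (from 2.92 to 301, log2 6.27), and Acta2, smooth muscle actin (from 11.4 to 763, log2 5.95). The largest falls were Inhbb (log2 -4.17), Prdm14, Esrrb, Jam2 (log2 -3.88) and Mymx, a muscle fusion micropeptide gene (log2 -3.86). Genes of the feeder fibroblast list rose in 13 of 19 cases with 0 falls (median 3.74), and the 6 that were not called were Dcn, Loxl1, Lum, Prrx1, S100a4 and Thy1. Cytoskeleton and epithelial-mesenchymal transition genes rose in 19 of 21 cases, Anxa1, an annexin, from 7.48 to 424 (log2 5.65). Immediate-early and stress genes rose in 13 of 16 cases, Atf3 from 47.7 to 311 (log2 2.68), beside a median of 0.47 for the 13 mitochondrially encoded genes, of which none was called and whose median lay above the central 95% of random lists; mt-Co1 and mt-Nd1, the most abundant, had -0.0495 and 0.00840. G2/M genes fell in 14 of 20, with a median log2 ratio of -0.59, and 15 of 19 microRNA pathway genes were not called. Quantile rescaling shifts the median gene of this comparison by -0.11 on the log2 scale and turns no named gene.

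**Figure D2:**
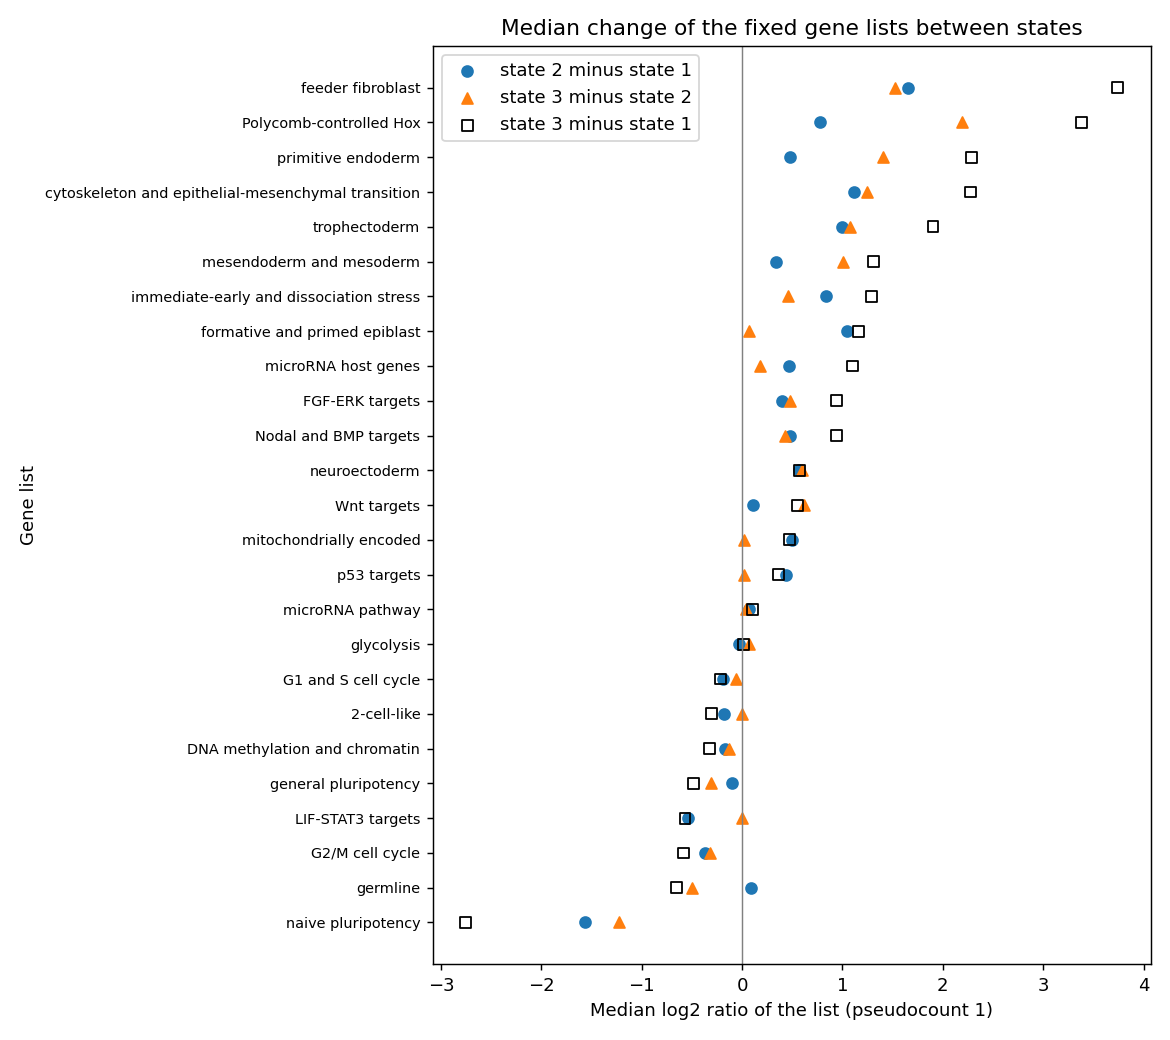
Median log2 ratio (value plus 1) of each gene list, with a circle for state 2 minus state 1, a triangle for state 3 minus state 2 and a square for state 3 minus state 1. The naive list has the lowest median at -2.75 for state 3 minus state 1, and the Hox list is at 0.78 for state 2 minus state 1 and 2.19 for state 3 minus state 2.

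The position of state 2 between the other states was measured on the 6070 genes called between state 3 and state 1. In the median gene, state 2 had covered 0.603 of the log2 distance from state 1 to state 3 (95% order-statistic interval 0.594 to 0.612 across genes, which are not independent). Joint probabilities were summed here from the authors' deposited patterns. At 0.95 or more, 1121 genes had state 2 equal to state 3 and state 1 apart, and 491 had state 2 equal to state 1 and state 3 apart. At the same limit 1043 had all 3 states apart and 5 had state 2 apart from equal states 1 and 3. Without a threshold, the probabilities summed over genes were 3945, 2382, 2343 and 153 in the same order, so the ratios between these counts depend on the threshold. Of genes called in both steps, 77 were highest in state 2, among them Dnmt3l and Neurod1, and 76 were lowest there, among them Cdx1, a caudal factor; these 3 were chosen after their values were seen. Both steps use the same state 2 libraries and no value per library was used, so the chance overlap of the steps could not be simulated.

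Against the unsorted total population, Nanog was higher in state 1 (log2 0.57) and lower in state 2 (log2 -1.90) and state 3 (log2 -2.66). Sox2 was lower in state 2 (log2 -0.32) and state 3 (log2 -1.60), with 4155 in state 1 against 3954 in the total population (not called). Pou5f1, at 12174 in the total population, was called in none of the 3 comparisons. Sums of the authors' deposited probabilities called 588 genes for state 1 (210 higher, 378 lower), 3303 for state 2 (1728 higher, 1575 lower) and 5671 for state 3 (3202 higher, 2469 lower).

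In the small RNA libraries, microRNA hairpins made up 65.0% of the column total in state 1, 58.4% in state 2, 38.7% in state 3 and 60.9% in the total population. Features of the rRNA class made up 7.82%, 10.4%, 25.7% and 10.7%, and fragments of protein-coding genes 4.56%, 6.35%, 9.18% and 5.56%. Of the protein-coding share, the single gene Lars2 held 1.12%, 1.60%, 2.79% and 1.16% of the column totals. Nearly all of the rRNA class was 1 feature, CT010467.1, with 7.62%, 10.2%, 25.3% and 10.5%, which was not called between the states. The rRNA features with a mean of at least 10 had a median log2 ratio of -0.50 for state 3 against state 1. The most abundant hairpin was mir-292a of the miR-290 to miR-295 cluster, the main microRNA cluster of mouse ESC (mir-290a to mir-295, chromosome 7, 3218626 to 3220841 in GRCm38), with 36.2% of the state 1 total. The deposited scale lies within 0.013 of a median-ratio scale over all features on the log2 scale, so hairpin changes are relative to a median set mostly by fragments of other RNAs. On a scale of the microRNA total they shift by 0.73, 0.98 and 1.70 for state 2 against state 1, state 3 against state 2 and state 3 against state 1. The miR-290 to miR-295 cluster made up 66.5% of that total in state 1 and 50.8% in state 3. Its own fall on the deposited scale thus enters the total and raises the shift of the other hairpins. On the median-hairpin scale the shifts are 0.40, 0.39 and 0.79.

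**Figure D3:**
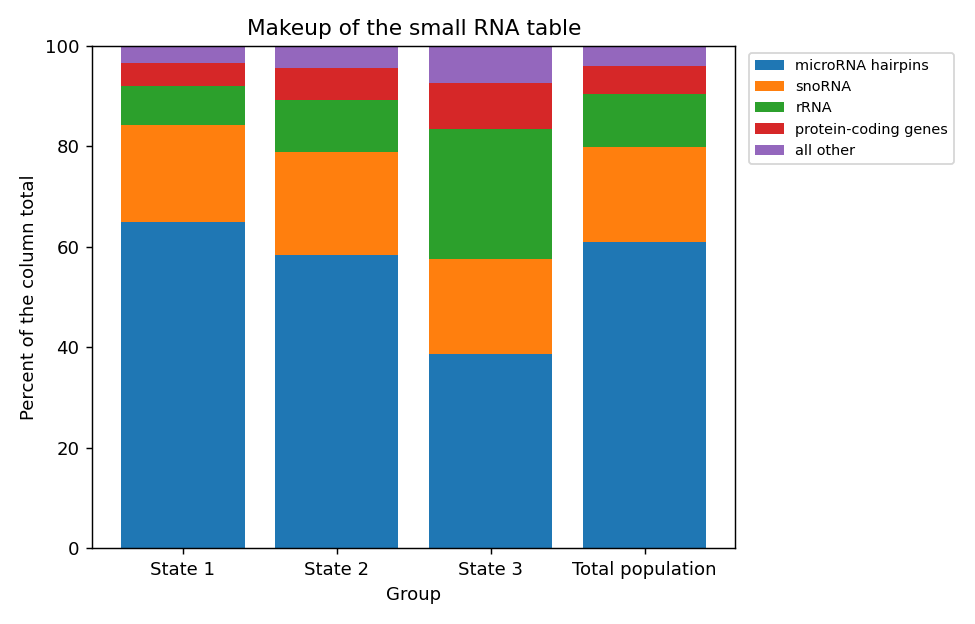
Stacked bars of the share of each RNA class in the column total of the small RNA table, in percent, for the 3 sorted states and the total population. Hairpins take 65.0% in state 1 and 38.7% in state 3, and the rRNA class 7.82% and 25.7%. The single rRNA feature CT010467.1 takes 7.62% and 25.3%.

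Between state 1 and state 2 the miR-302 cluster, microRNAs of the primed epiblast, rose in 3 of 5 hairpins under every scaling tried, mir-302b (chromosome 3, 127545228 to 127545301) from 170.5 to 898 (log2 2.39) and mir-302d from 48.8 to 212 (log2 2.10). The miR-183 cluster fell in 3 of 3 hairpins, mir-183 (chromosome 6, 30169668 to 30169737) from 154336 to 58489 (log2 -1.40). The let-7 family, which opposes Lin28 and the ESC program, fell in 8 of 12 hairpins, let-7g from 1384 to 487 (log2 -1.51). Of its named members let-7i turned to 0.12 on the microRNA-total scale. The let-7 median (-0.85) and the miR-290 to miR-295 median (-0.89) lay within the central 95% of random hairpin lists. In the miR-290 to miR-295 cluster 3 of 9 hairpins fell, mir-292a at -0.84 on the log2 scale, and in the Sfmbt2 intronic cluster 4 of 39 rose, mir-669c (chromosome 2, 10509296 to 10509404, within Sfmbt2) from 2706 to 7418 (log2 1.45).

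Sums of the authors' deposited probabilities called 183 small RNA features between state 2 and state 1 (60 higher, 123 lower in state 2). Of these 73 were hairpins (15 higher, 58 lower). Besides miR-302, the largest rises were mir-375, a microRNA of endocrine and endodermal cells (from 22.7 to 213, log2 3.17), and mir-9-2 and mir-9-3 (log2 4.21 and 4.23), whose value cannot be separated from mir-9-1, which shares their mature sequence. The largest falls were mir-196a-1 and mir-196a-2 of the Hox clusters (from 1732 to 370.3, log2 -2.22, and from 1297 to 284, log2 -2.19), mir-124-3 and mir-124-1, hairpins of a neuronal microRNA (log2 -2.20 and -1.96), and mir-150 (log2 -1.93). Copies of mir-196a and mir-124 also share mature sequences. In the other lists, 3 of 14 miR-17-92 and paralogous hairpins fell (1 turned higher on the microRNA-total scale), 1 of 7 of the miR-15/16 family fell, 3 of 34 differentiated-tissue hairpins rose and 4 fell, and none was called among 36 hairpins of the Dlk1-Dio3 cluster, 5 of the miR-200 family and 9 of the X-linked Fx-mir cluster. The differentiated-tissue hairpin mir-21a had values of 14545 in state 1, 37008 in state 2 and 40047 in state 3 and was not called in any of the 3 comparisons.

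Between state 2 and state 3 called hairpins mostly fell on the deposited scale. The miR-290 to miR-295 cluster fell in 5 of 9 hairpins, mir-293 from 83424 to 27843 (log2 -1.58), with 1, mir-292b, turning higher on the microRNA-total scale. The let-7 family fell in 9 of 12, let-7i from 549 to 146 (log2 -1.91). The miR-183 cluster fell in 3 of 3, mir-182 from 14177 to 5651 (log2 -1.33). On the microRNA-total scale mir-183 and mir-96 turned to 0.13 and 0.017. The miR-183 median (-0.97) and the miR-290 to miR-295 median (-1.14) lay within the central 95% of random hairpin lists. The let-7 median lay below it. The X-linked Fx-mir cluster, a germline-expressed group, fell in 5 of 9, mir-881 from 92.8 to 24.0 (log2 -1.91); the other 4 are the copies of mir-465b and of mir-465c, and the copies of each hold identical values and are not separate members. Of the miR-200 family, which maintains epithelial character, 2 of 5 fell, mir-200a from 1246 to 434 (log2 -1.52) and mir-200c from 993 to 326 (log2 -1.61), and 4 of 39 of the Sfmbt2 cluster fell, mir-669c from 7418 to 2623 (log2 -1.50).

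Sums of the authors' deposited probabilities called 255 features in this step (80 higher, 175 lower in state 3). Of these 95 were hairpins, 4 higher and 91 lower, or 4.21% higher. On the microRNA-total scale 20% of those hairpins were higher. The 4 that rose were mir-351 (from 16.5 to 54.2, log2 1.66), mir-196b (from 25.2 to 77.0, log2 1.57), mir-504 (from 57.4 to 141, log2 1.29) and mir-212 (from 54.3 to 92.2, log2 0.75). The largest falls were mir-374c (log2 -2.35), mir-150 (log2 -2.00), mir-195a (log2 -1.92), mir-881 and let-7i. None of the 5 miR-302 cluster hairpins was called, with mir-302b at 898 in state 2 and 992 in state 3. In the other lists 3 of 14 miR-17-92 and paralogous hairpins and 2 of 7 miR-15/16 hairpins fell, with 0 rises in each. Falls were called in 4 of 36 Dlk1-Dio3 hairpins and 3 of 34 differentiated-tissue hairpins, again with 0 rises. On the microRNA-total scale 1 miR-17-92 and paralogous hairpin, mir-106b, and 1 differentiated-tissue hairpin turned higher. The differentiated-tissue median of -0.21 lay above the central 95% of random hairpin lists, as did its medians in the other comparisons between states.

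Between state 1 and state 3 all 9 hairpins of the miR-290 to miR-295 cluster fell, mir-292a from 1855076 to 430145 (log2 -2.11), and 2 of them turned higher on the microRNA-total scale. On both scales 9 of 12 let-7 hairpins, 3 of 3 of the miR-183 cluster and 5 of 9 of the Fx-mir cluster (the same hairpins, copies included) fell, let-7g from 1384 to 156 (log2 -3.14) and mir-182 from 33600.2 to 5651 (log2 -2.57). The miR-302 cluster rose in 3 of 5 hairpins on both, mir-302d from 48.8 to 310.2 (log2 2.64). Against random hairpin lists, the miR-302, let-7 and Fx-mir medians lay outside the central 95%. Those of miR-290 to miR-295 (-2.05) and miR-183 (-2.38, at its lower limit) did not. Called members of the other families fell on the deposited scale and in part turned higher on the microRNA-total scale: 5 of 14 miR-17-92 and paralogous hairpins (4 turned), 5 of 7 miR-15/16 hairpins (2 turned), 5 of 36 Dlk1-Dio3 hairpins (all 5 turned) and 1 of 5 miR-200 hairpins (1 turned).

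Sums of the authors' deposited probabilities called 428 features between state 3 and state 1 (145 higher, 283 lower in state 3). Of these 153 were hairpins, 17 higher and 136 lower. On the deposited scale 11.1% of the hairpins were higher, against 47.1% on the microRNA-total scale. On the median-hairpin scale 4 of the 153 turned. The largest rises were mir-615 (chromosome 15, 103014910 to 103015001, beside the Hoxc genes), from 1.49 to 64.4 (log2 4.71), the mir-9-2 and mir-9-3 copies, mir-297a-4 (from 4.77 to 69.9, log2 3.62) and mir-483, which lies in Igf2 (from 15.3 to 181, log2 3.48). The largest falls were mir-150 (from 1963 to 128, log2 -3.93), mir-196a-2 (log2 -3.33), mir-3078 (log2 -3.32), mir-196a-1 (log2 -3.30) and mir-124-1 (log2 -3.24). Of 34 differentiated-tissue hairpins 4 rose and 7 fell, with 2 of the latter turning higher on the microRNA-total scale, and 1 of 39 Sfmbt2 hairpins rose.

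**Figure D4:**
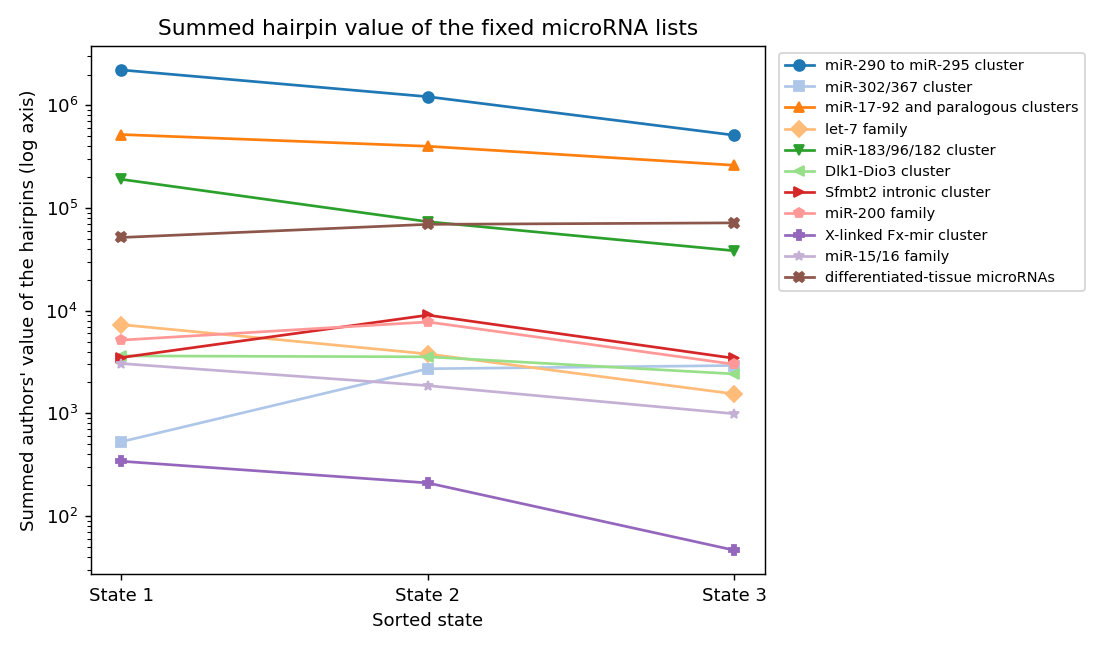
Sum of the authors' values over the hairpins of each microRNA list in the 3 sorted states, on a log axis; lines join the sums of a list. The miR-302 cluster sum is 528 in state 1 and 2922 in state 3, and the let-7 sum 7309 and 1544; the downward slopes of the abundant lists depend on the scale, and on the microRNA-total scale some of their hairpins turn higher.

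Among the 153 hairpins called between state 3 and state 1, state 2 had covered 0.458 of the log2 distance in the median hairpin (95% order-statistic interval 0.415 to 0.486 across hairpins). The fraction was 0.794 in the 17 hairpins that rose (0.439 to 0.9899) and 0.447 in the 136 that fell (0.407 to 0.480). This split depends on the scale, since 55 of the 153 turned on the microRNA-total scale, and the risers include mir-9-2 and mir-9-3. Against the total population, sums of the authors' deposited probabilities called 51 small RNA features for state 1, 15 of them hairpins (9 higher, 6 lower). The sums called 148 for state 2, 47 of them hairpins (6 higher, 41 lower), and 362 for state 3, 132 of them hairpins (6 higher, 126 lower). Of the state 3 hairpins, 4.55% were higher than in the total population on the deposited scale and 33.3% on the microRNA-total scale.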

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

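The test in this part was set before its result was seen. The small RNA libraries also hold fragments of messenger RNA, which enter the comparisons above only in counts and class shares: 6821 protein-coding genes lay above the value that 3 reads allow in every group, the limit that a count of 0 allows. In state 1, state 2 and state 3, fragments of Nanog were 49.5, 17.6 and 22.3, of Sox2 66.8, 64.3 and 29.6 and of Pou5f1 86.8, 81.0 and 74.6, and none of these differences was called. The small RNA libraries are separate from the RNA-seq libraries. Of 211 protein-coding genes called between state 3 and state 1 with an absolute log2 ratio of at least 1 and a mean fragment value of at least 10, 92.9% had the same direction in the fragments (95% Wilson interval 88.6% to 95.6%, with genes not independent). Genes that rose had a median fragment log2 ratio of 1.43 and genes that fell -0.82. For state 2 against state 1 the share was 94.0% of 83 genes, and for state 3 against state 2 83.7% of 43. Across all 3114 genes with such fragments, Pearson's r between the log2 ratios of the 2 tables was 0.550 for state 3 against state 1, 0.446 for state 2 against state 1 and 0.295 for state 3 against state 2; these are correlations across genes, which are not replicates.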

How the results depend on the processing

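No paired analysis was possible because the tables hold a single value per group and no column carries a replicate letter. For the same reason DESeq2 and edgeR, the other count filters and size factors, the 2-group fits, the fits without each replicate, camera with an estimated correlation and other splits of the samples were not run. The threshold of 0.99, the most probable pattern and the median-hairpin scale were chosen after seeing the data. With an absolute log2 ratio of at least 1, the RNA-seq counts were 1465, 839, 2766, 196, 724 and 2202 for state 2 against state 1, state 3 against state 2, state 3 against state 1, and state 1, state 2 and state 3 against the total population, fewer by construction. With hairpins alone, the small RNA counts in the same order were 73, 95, 153, 15, 47 and 132, from fewer features. Calls from the most probable pattern gave 1088 genes for state 1 against the total population and 92 and 233 small RNA features for state 1 and state 2 against it; the cause was not tested. Counts with a threshold of 0.99, a mean of at least 5 or protein-coding genes alone stayed within 1.5 times of those reported, as did the numbers of lists outside the random range. On the microRNA-total scale, the share of higher calls in the small RNA table was 46.3% for state 3 against state 2, 63.3% for state 3 against state 1 and 51.1% for state 3 against the total population (from 31.4%, 33.9% and 28.5%), and among hairpins 20%, 47.1% and 33.3%. The scale adds its shift to every hairpin and turned 4, 15 and 55 called hairpins for state 2 against state 1, state 3 against state 2 and state 3 against state 1. Of the named ones it turned for state 2 against state 1 let-7i to 0.12; for state 3 against state 1 mir-292b to 0.18, mir-106b to 0.29, mir-379 to 0.65, mir-381 to 0.96, mir-200a to 0.92, mir-16-1 to 0.42 and mir-15b to 0.38; for state 3 against state 2 mir-292b to 0.23, mir-106b to 0.38, mir-183 to 0.13 and mir-96 to 0.017. On the median-hairpin scale 1, 0 and 4 turned, of the named ones mir-381 to 0.041 for state 3 against state 1. The median fraction of state 2 was 0.584 in RNA-seq with quantile rescaling, and in hairpins 0.377 with quantile rescaling and 0.390 on the microRNA-total scale; the cause was not tested. Under median-ratio, quantile and pseudocount alternatives no called gene named here changed sign, except that mir-292a, the top feature of state 1 and state 2, has a ratio of 0 under quantile rescaling. A limit of these results is that the spread between libraries is not in the values used.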

Other observations

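Tests of the microRNA, mir-9 and fibroblast patterns were chosen after those results were seen, and the test of the total population before. The genes and hairpins of this paragraph were chosen after their values were seen. Hairpins in the Hox clusters did not all move with the Hox genes: mir-615 rose from 1.49 to 64.4 and mir-196b from 34.6 to 77.0 between state 1 and state 3, as Hoxa9, beside mir-196b, rose from 1.92 to 35.2. Hoxc5, beside mir-615, was 0 in state 1 and 9.60 in state 3 and was not called. The mir-10b hairpin rose from 119 to 506, while Hoxd4, whose interval holds it, was 0.640 and 4.45 (not called). The mir-10a hairpin was 1026 and 2375 (not called) where Hoxb4, beside it, rose from 2.89 to 32.4. That hairpin lies within the interval of Hoxb3, which was not set against it here. In contrast mir-196a-1 and mir-196a-2 fell, to 175 and 128, while Hoxb9 and Hoxc9, the Hox genes next to them, rose from 33.9 to 68.3 and from 0.330 to 13.7. Hairpin and host also parted at Sfmbt2 on the deposited scale: mir-669c was 2706, 7418 and 2623 in state 1, state 2 and state 3, and called lower in state 3 than in state 2, where Sfmbt2 was 568, 2133 and 1879 and was not called in that step. At Igf2, an imprinted growth factor gene, host and hairpin both rose between state 1 and state 3, Igf2 from 227 to 5784 and mir-483 from 15.3 to 181. On the microRNA-total scale mir-669c had log2 ratios of -0.51 for state 3 against state 2 and 1.68 for state 3 against state 1, nearer to those of Sfmbt2 (-0.18 and 1.73). The directions of the other hairpins hold on that scale.

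MicroRNA hairpins with a mean of at least 10 had a median log2 ratio of -1.02 between state 3 and state 1. More mRNA fragments in the state 3 libraries could lower every short RNA alike on the deposited scale, which lies near a median over all features. The gain in rRNA share came nearly all from 1 feature, which barely moves such a median. Part of the gain in protein-coding share likewise came from 1 gene, Lars2 (1.12% in state 1 and 2.79% in state 3). The snoRNA features had a median of -0.55, between the values that fragment content and its opposite call for. With no spike-in in the values used, these 2 cannot be told apart for the class as a whole. A single scale cannot part families: the miR-302 cluster median exceeded the let-7 median by 4.72 on the log2 scale, which argues against fragment content as the whole cause of that difference. The state itself stays open as an untested explanation of it.

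The mir-9-2 and mir-9-3 hairpins rose by 4.03 and 4.06 on the log2 scale between state 1 and state 3, while mir-9-1 fell from 1357 to 323. The 3 hairpins share a mature sequence, and their sum had a log2 ratio of -0.52, smaller than that of each copy, but 1.198 on the microRNA-total scale. Reads divided differently among the copies may account for the rises, since mir-9-1 held 97.3% of the sum in state 1 and 33.2%, 33.4% and 33.3% in state 2, state 3 and the total population. In the total population mir-9-2 and mir-9-3 were 480 and 483, above their values in every sorted state. If the total population is a mixture of the states, this argues against a rise of these copies of their own. Whether the mature microRNA itself rose or fell depends on the scale and stays open, as does the state as an untested biological explanation.

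Genes of the feeder fibroblast list rose through the states, and fibroblasts in the sorted gates are a candidate source, beside the state itself, which was not tested. A single source would give every gene a like ratio of the gain from state 2 to state 3 over the gain from state 1 to state 2; among the 13 members called between state 3 and state 1 it ran from 0.352 to 8.54, a 24.3-fold range, and among the 6 called in both steps 3.65-fold. The rule asked for a wide range in both sets to count against a single source, and the 3.65-fold range fell short of its limit. The lowest members of the wider range, Col6a1, Mmp2 and Col6a2, were not called in the step from state 2 to state 3. Without the spread between libraries the test cannot decide, and the question stays open. An earlier test was dropped because its genes had been picked for not being called: Dcn, Lum, Prrx1, S100a4 and Thy1 together gained 0.214% and 0.733% of the gain of Tagln and Thbs1 in the 2 steps, which would have argued against fibroblasts. Of the 19 list members, 10 had a value of at least 5 in state 1 and 0 were in another list. The labels do not say whether feeders were used, and a gate on high Sox2, as for state 2, would remove fibroblasts. If it did, the ratio of the 2 gains could not inform on fibroblasts in state 3.

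If the total population were a mixture of the 3 sorted states, its values should lie between theirs. Of 6070 genes called between state 3 and state 1, 87.5% had a total population value within the range of the states (95% Wilson interval 86.6% to 88.3%), against 64.5% of 10840 uncalled genes with a mean of at least 5. This fell short of the 90% set before the result was seen and stayed above the 75% set against the mixture, so it is undecided. Below the range lay 461 genes and above it 300. Called genes were chosen for a wide range between states, which by itself raises their share over that of uncalled genes. A non-negative fit of the called genes weighted state 1, state 2 and state 3 by 0.735, 0.162 and 0.0354, which sum to 0.932, and 96.2% of the fitted genes lay within 1.5-fold of that fit. The fit was scored on the genes it was fitted to, and no fit on state 1 alone was set beside it. Since only 588 genes were called between state 1 and the total population, this share cannot separate a mixture from closeness to state 1. The mRNA fragments of the small RNA libraries, described above with 92.9% of genes in the same direction, are the other hypothesis tested.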
